A study of Mus musculus with 6 samples.

How the data were processed

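RNA sequencing of kidney tissue from wild-type mice was analysed in 6 samples, 3 controls and 3 treated with cisplatin. Total RNA was extracted from the kidneys with a commercial kit, per the labels' protocols. Sequencing reads were aligned with HISAT (version not given in the sources used here) to the mouse build GRCm38.p6, per the submitters' processing notes. Library strandedness, the gene annotation and the counting program are not given in the sources used here.

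The authors deposited 1 table with 19087 genes. For each library it held estimated counts of reads per gene, FPKM and TPM, per the file headers. The estimated counts deposited by the authors were not normalized: between 66.2% and 67.7% of values per library were exactly whole, the rest had decimals, and library totals differed. The FPKM values deposited by the authors are fragments per kilobase of transcript, scaled to library size. The TPM values deposited by the authors had the same total in each library and entered no test. Columns were matched to samples by name. The control columns carry only initials and a number, read as wild type and control, since the other columns name cisplatin and the series has 2 groups. Of the gene identifiers (Entrez IDs), 19031 (99.7%) were found in the RefSeq annotation of GRCm38.p6, which gave positions and lengths, and 99.3% of those were protein coding. No mitochondrially encoded gene was in the table, so the fixed list of these genes had no member to test. Of 704 symbols in all lists 22 were not found, and older or newer symbols were used where the listed one was absent.

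Library totals of estimated counts ranged from 16725614 to 18523618. A floor of 3 counts over a group corresponds to 0.0615 CPM (normalized counts scaled to library size) in the controls and 0.0524 CPM in cisplatin. Folds against a group with 0 counts were computed against that floor from the counts pooled over each group's libraries, which can differ slightly from the ratio of the mean CPM to the floor, and for groups with 1 to 3 counts an exact (Clopper-Pearson) 95% interval of the pooled count ratio is given. Such floors and intervals cover counting error only. Counts of replicate pairs within a group differed by 8.66 to 53.2 times the sampling variance (chi-square per degree of freedom), so no library was a copy of another.

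Estimated counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr (minimum count 10), which left 14392, normalized with TMM factors and compared with the quasi-likelihood F test of edgeR 4.0.16 (robust, two-sided) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and a log2 fold change of at least 1 was the further threshold for 2-fold changes. The biological coefficient of variation was 0.12. Means and SDs are of TMM-normalized CPM over the 3 libraries of a group. In simulated counts with the control means, library sizes and gene-wise dispersions of the real data (14392 genes tested), the procedure recovered 56.7% of 67 genes changed by 1.5-fold, 89.6% of 67 changed by 2-fold and 92.4% of 66 changed by 4-fold, with 19 false calls, and 2 of 100 random lists had p under 0.05. Those 19 stood beside 38, 60 and 61 recovered genes, a larger false share than the threshold of 0.05. Far fewer genes were changed there, equally up and down, than the 6527 called in the real data. Error control and scaling under so wide a change were therefore not tested.

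Before the files were opened, 20 pathway lists, 17 cell type lists and 3 technical lists were fixed. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01), adjusted over the pathway and cell type lists. The same test with a correlation estimated per list, fry, and camera on lists without members that another list also holds were alternatives. Counts of members are given after adjustment over all genes and over the list alone.

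The rule for named genes was fixed at the same time. It took Havcr1, Lcn2 and the 4 chemerin genes whatever their values. It then took the 5 largest rises and 5 largest falls among called genes with an official symbol, at least 5 CPM in the higher group and no overlap between groups (chance gives no overlap in 10% of genes with 3 against 3 samples). Of each pathway list it took the 2, and of each cell type list the 1, called member with the largest change and at least 1 CPM in the higher group. Called members in the direction with fewer calls were named where there were 2 or fewer, and a list without a called member gave its most expressed member. Some genes that this rule picked are not reported here. Globin, Saa, Gsta and Cyp4a genes have near-identical copies, Rarres2, Fosl1, Timp1, Dbp, Prc1, Idh3b and Gpr1 overlap another gene with an official symbol in the annotation, and Cmklr1, Fhit, Egf, Ndufs1, Rrm2b, Cyp4a14, Isg15, Top2a, Postn, Cidec, Npas2, Egr2, Kdr, Flt1, Ptpro, Itga8, Trpv5 and Aqp4 overlap a predicted, antisense or pseudogene locus, so their counts are uncertain where reads could be split between them.

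The alternatives were DESeq2 size factors, upper-quartile factors or library size only in the same test, the Wald test of DESeq2 1.42.0 with its own filters, limma-voom, no filter on low counts, at least 1 CPM in at least 3 libraries, the replicate number as a block, leaving out each library in turn, and limma on the log2 of the authors' FPKM plus 1 for genes of at least 1 FPKM in at least 3 libraries. Exact permutation tests used all splits of 3 against 3 samples, whose smallest two-sided p is 0.1. Transcript length and GC content for the check of gene length came from GENCODE M21. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.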

Results

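Messenger RNA of kidney tissue was measured by RNA sequencing in 6 wild-type mouse samples, 3 labelled as controls and 3 labelled as treated with cisplatin, a platinum drug that cross-links DNA and injures the kidney tubule. Cisplatin was injected into the peritoneal cavity to induce acute kidney injury, and the comparison was meant to find molecules that make mice on a high-fat diet more sensitive to such injury. Dose, time after injection, sex and diet of these mice are not given in the sources used here. The table held 19087 genes, and the estimated counts per library summed to 17109847, 17351751 and 16725614 in control replicates 1 to 3 and to 18523618, 18340806 and 17775966 in cisplatin replicates 1 to 3. The labels name separate samples without saying that each came from its own animal, so p-values measure the spread between these samples, which may be partly technical.

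Cisplatin-treated kidneys had far more transcripts of tubule injury markers, p53 targets and acute phase proteins than control kidneys, and fewer transcripts of tubule transporters and mitochondrial enzymes. The set test camera called these lists with its preset correlation between genes, but with an estimated correlation it called none of them (adjusted p = 0.349, 0.149, 0.0884, 0.468 and, for both mitochondrial lists, 0.449). Havcr1, which encodes kidney injury molecule 1, rose from 2.67 ± 0.54 to 976 ± 519 CPM (normalized counts scaled to library size; mean ± SD, n = 3 per group), a log2 fold change of 8.51 (SE 0.60; edgeR adjusted p = 0.000126). Lcn2, which encodes the injury marker neutrophil gelatinase-associated lipocalin, rose from 9.07 ± 2.28 to 389 ± 135 CPM (log2 fold change 5.42, SE 0.35; edgeR adjusted p = 6.84e-05). Both genes were higher in 3 of 3 cisplatin libraries than in every control library. Of 14392 genes tested, 3326 were higher and 3201 lower in cisplatin at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and 1070 and 772 of these differed by at least 2-fold. Without composition factors, scaling to library size gave 4632 higher and 2281 lower genes, or 67.0% higher against 51.0% with TMM factors, because that scaling moved the median of all genes up by 0.14 on the log2 scale. On the authors' FPKM values, limma called 4170 higher and 2080 lower genes, 66.7% of them higher, with 329 lower by at least 2-fold.

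On the first principal component, which held 83.6% of the variance, the controls lay at -45.5, -43.6 and -41.5 and the cisplatin libraries at 45.5, 53.6 and 31.4. The library at 31.4 was cisplatin replicate 3, in which Havcr1 reached 420 CPM against 1060 and 1449 CPM in the other 2 cisplatin libraries. Leaving that library out gave 3614 higher and 3591 lower genes.

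**Figure D1:**
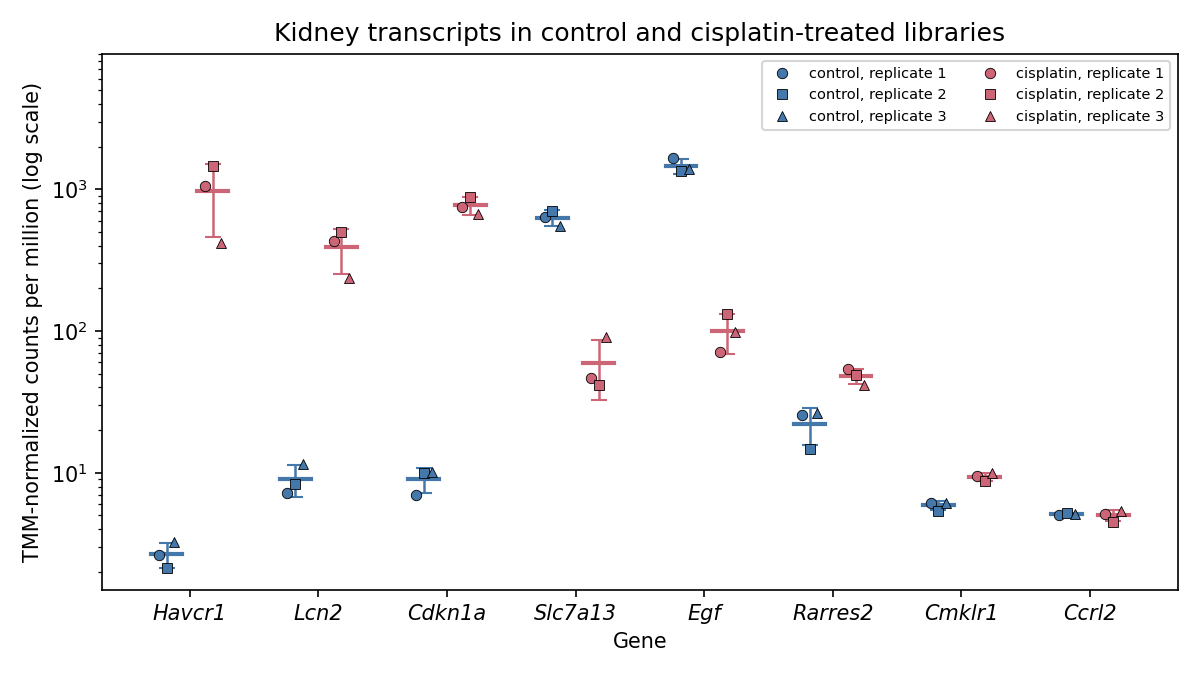
Normalized CPM (log scale) of 8 genes in the 3 control and 3 cisplatin libraries; each point is a library, each horizontal bar the group mean and each vertical bar the SD. Havcr1, Lcn2, Cdkn1a, Rarres2 and Cmklr1 were higher and Slc7a13 and Egf lower in cisplatin, with no overlap between the groups, while Ccrl2 overlapped.

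The largest rises among well-expressed genes were those of Saa1, Fosl1, Crct1, Krt20 and Havcr1. Saa1, which encodes an acute phase apolipoprotein, had no count in the controls and 20.04 ± 2.43 CPM in cisplatin, at least 326-fold higher against a floor of 3 counts over the group. Crct1, an epidermal differentiation gene, also had no control count and reached 7.60 ± 5.17 CPM, at least 127-fold higher. Fosl1, which encodes the AP-1 subunit Fra-1, had 1 count in all controls together and 56.6 ± 35.0 CPM in cisplatin, a ratio of 2832 with a 95% counting interval of 508 to 111880. Krt20, a keratin of injured tubule cells, rose from 0.78 ± 0.19 to 291 ± 137 CPM (log2 fold change 8.53). The Crct1 call was lost without cisplatin replicate 2 (adjusted p = 0.0866 in edgeR; 7.65e-08 to 0.0866 over all alternatives), and Fosl1's only control count lay in control replicate 1.

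The largest falls were those of 4 globin genes and Fhit. Hba-a2 averaged 84.2 ± 75.1 CPM and Hbb-bt 13.1 ± 12.3 CPM in the controls, and neither had a count in cisplatin, at least 1616-fold and 251-fold lower. Hbb-bs fell from 131 ± 129 to 0.13 ± 0.14 CPM and Hba-a1 from 121 ± 116 to 0.24 ± 0.05 CPM (log2 fold changes -9.99 and -8.92). Globins are the oxygen carriers of red blood cells, and their near-identical copies can share reads. Globin calls were lost without cisplatin replicate 2 (edgeR adjusted p = 0.127 for Hba-a2, 0.143 for Hbb-bt, 0.0697 for Hbb-bs and 0.0705 for Hba-a1) or cisplatin replicate 3 (0.114, 0.119, 0.0584 and 0.0618), although every cisplatin library lay below every control library; over all alternatives the highest were 0.127, 0.143, 0.153 and 0.160. Without control replicate 1 the log2 fold changes of Hba-a2, Hbb-bt, Hbb-bs and Hba-a1 were -12.62, -9.82, -8.89 and -7.88, and without cisplatin replicate 3 that of Hbb-bs was -11.16. Fhit, a diadenosine triphosphate hydrolase gene of 1612 kb (Entrez 14198, chromosome 14, 9550092 to 11162061, GRCm38.p6), fell from 11.3 ± 2.0 to 0.08 ± 0.08 CPM (log2 fold change -6.90, SE 0.39; edgeR adjusted p = 8.69e-06; -7.54 without cisplatin replicate 2).

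The series title names chemerin, the chemoattractant protein that Rarres2 encodes, and its message was about 2.17-fold higher in cisplatin. Rarres2 (Entrez 71660, chromosome 6, 48569696 to 48572845, GRCm38.p6) averaged 22.2 ± 6.4 CPM in the controls and 48.1 ± 6.1 CPM in cisplatin. Its log2 fold change was 1.12 (SE 0.22), with an edgeR adjusted p of 0.00551 over all genes and 0.00188 adjusted over the list alone. It was higher in 3 of 3 cisplatin libraries (53.8, 48.7 and 41.7 CPM) than in every control (25.5, 14.8 and 26.3 CPM), and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 samples allow. Cmklr1, which encodes the signalling chemerin receptor (Entrez 14747, chromosome 5, 113612355 to 113650475), rose from 5.88 ± 0.43 to 9.41 ± 0.59 CPM (log2 fold change 0.68, SE 0.13; edgeR adjusted p = 0.00315). Ccrl2, which encodes a chemerin-binding receptor (Entrez 54199, chromosome 9, 111054834 to 111057518), had 5.14 ± 0.07 CPM in the controls and 5.02 ± 0.46 CPM in cisplatin (log2 fold change -0.03, SE 0.14; edgeR adjusted p = 0.863). Gpr1, a further chemerin receptor gene (Entrez 241070, chromosome 1, 63182571 to 63223278), was under the count filter, with 1 count over the controls and 6 over cisplatin, a ratio of 5.11 with a 95% counting interval of 0.62 to 235. With adjustment over the list alone the count was also 2 higher and 0 lower of 3 tested. Rarres2 overlaps Lrrc61 in the annotation, so reads of the pair may not be fully separated.

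Of the targets of p53, the transcription factor that responds to DNA damage, 24 of 26 tested members were higher, 1 was lower and 1 was not called (median log2 fold change 2.23). Camera gave the list an adjusted p of 9.71e-16 with the preset correlation and of 0.149 with an estimated correlation. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 9.04 ± 1.80 to 771 ± 110 CPM (log2 fold change 6.41, SE 0.20; edgeR adjusted p = 5.69e-07), and Psrc1 from 0.88 ± 0.10 to 48.5 ± 10.1 CPM (5.77). Rrm2b, a ribonucleotide reductase subunit gene, was the member that fell (-0.40), a call lost on the authors' FPKM (limma adjusted p = 0.0663). Among kidney injury and tubule repair markers, 29 of 30 were higher and 1 was not called (median 3.71), led by Krt20 and Havcr1, with an adjusted p of 9.71e-16 and of 0.349 with an estimated correlation. In cisplatin replicate 3 the injury markers lay a median of 0.73 below the mean of the other 2 cisplatin libraries on the log2 scale, and the p53 targets 0.14 below it. Counted by significance adjusted over the list alone, 25 p53 targets and 29 injury markers were higher and 1 and 0 lower.

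Complement and acute phase genes were higher in 18 of 19 members and lower in none (median 3.18; adjusted p = 8.16e-12 in camera and 0.0884 with an estimated correlation). Saa1 led, and Saa2, its close copy with which it can share reads, had no control count and 1.60 ± 0.37 CPM in cisplatin, at least 26.1-fold higher. Immediate early genes, transcribed within minutes of a stimulus, were higher in 13 of 15 members (median 2.07; adjusted p = 8.16e-07, and 0.294 with an estimated correlation). Atf3 rose from 1.41 ± 0.24 to 25.8 ± 2.0 CPM and Egr2 from 0.43 ± 0.24 to 7.20 ± 2.38 CPM. With that adjustment over the list alone, 19 acute phase and 13 immediate early genes were higher and 0 lower. With members at 0 to 3 counts in a group set to their bound, the median of the acute phase list was still 3.18.

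Chemokine and cytokine genes were higher in 16 of 25 tested members and lower in 2 (median 1.13, also with members at 0 to 3 counts in a group at their bound). The list had an adjusted p of 9.46e-06 in camera and of 0.294 with an estimated correlation. Ccl20, a chemoattractant of dendritic and T cells, had no control count and 1.73 ± 0.79 CPM in cisplatin, at least 28.4-fold higher, and Lif, a cytokine of the interleukin-6 family, rose from 0.47 ± 0.34 to 38.1 ± 11.3 CPM (log2 fold change 6.32; 7.07 without control replicate 2). Cxcl12 fell from 192 ± 7 to 117 ± 29 CPM (-0.72) and Cxcl9 from 6.23 ± 4.11 to 1.52 ± 0.62 CPM (-2.02). The Cxcl9 call was lost without cisplatin replicate 1 or 3 (edgeR adjusted p = 0.0669 and 0.0683; 0.000191 to 0.0683 over all alternatives), and without control replicate 3 its log2 fold change was -1.38. Type I interferon response genes were higher in 17 of 20 members and lower in none (adjusted p = 3.41e-07, and 0.449 with an estimated correlation), including Irf7, which rose from 38.1 ± 7.3 to 222 ± 80 CPM, and Isg15, from 5.45 ± 2.03 to 29.4 ± 7.2 CPM. Counts adjusted over the list alone were the same for both lists.

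Genes of the NRF2 and oxidative stress response were higher in 16 of 21 members and lower in 1 (median 1.05; camera adjusted p = 1.27e-07, and 0.247 with an estimated correlation). Gsta1, a glutathione S-transferase gene with a near-identical copy in Gsta2, rose from 0.67 ± 0.30 to 60.7 ± 7.8 CPM, and the metallothionein gene Mt2 from 68.4 ± 10.4 to 579 ± 132 CPM. Ftl1, which encodes ferritin light chain, fell by 0.52 on the log2 scale, a call lost without control replicate 1, control replicate 3 or cisplatin replicate 1 (edgeR adjusted p = 0.0566, 0.0829 and 0.109; 0.000294 to 0.109 over all alternatives). The unfolded protein and integrated stress response list had 12 of 19 members higher and none lower (median 0.69; adjusted p = 8.56e-05, and 0.149 with an estimated correlation). Psat1, a serine synthesis enzyme gene, rose by 1.64 and Sesn2 by 1.40 on the log2 scale. Of the regulated cell death genes, 12 of 20 were higher and none lower (median 0.54; adjusted p = 0.00248, and 0.247 with an estimated correlation). Mlkl, the executor of necroptosis, rose from 2.17 ± 0.63 to 13.4 ± 4.9 CPM, and Acsl4, a lipid enzyme needed for ferroptosis, from 30.2 ± 1.2 to 98.5 ± 9.3 CPM. In these 3 lists 17, 13 and 12 members were higher and 1, 0 and 0 lower when adjusted over the list alone.

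Transporters and brush border genes of the proximal tubule, the segment that takes up most of the filtrate, were lower in 27 of 36 members and higher in 4 (median -0.86; camera adjusted p = 6.07e-07, and 0.468 with an estimated correlation). Slc7a13, an aspartate and glutamate transporter gene, fell from 629 ± 81 to 59.3 ± 26.7 CPM (log2 fold change -3.41, SE 0.32, edgeR adjusted p = 0.000285), and the organic anion transporter gene Slc22a30 from 215 ± 32 to 35.2 ± 19.2 CPM (-2.61). In cisplatin replicate 3 the list lay a median of 0.52 above the mean of the other 2 cisplatin libraries. Among enzymes of gluconeogenesis and kidney amino acid metabolism, 9 of 21 were lower and 4 higher (median -0.43; camera adjusted p = 0.0286, and 0.661 with an estimated correlation). Gatm, of creatine synthesis, fell from 574 ± 50 to 127 ± 23 CPM. In cisplatin replicate 3 the enzymes lay a median of 0.54 above the mean of the other 2 cisplatin libraries. That list's call was lost without cisplatin replicate 2 (camera adjusted p = 0.0820; 0.00101 to 0.0820 over camera's alternatives other than the estimated correlation) and with fry, which tests a list's own genes against no change (0.0931). By the adjustment over each list alone, 29 transporters and 9 enzymes were lower and 4 and 4 higher.

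Nuclear genes for mitochondrial respiration fell together and by small amounts. Of 40 oxidative phosphorylation subunits, 38 were lower and none higher (median -0.56), with an adjusted p of 1.60e-13 in camera and of 0.449 with an estimated correlation. Ndufs1 of complex I fell from 237 ± 12 to 129 ± 15 CPM and Sdhb of complex II from 447 ± 12 to 255 ± 37 CPM. All 17 genes of the tricarboxylic acid cycle list were lower (median -0.55; adjusted p = 2.38e-07, and 0.449 with an estimated correlation), including Idh2 (-1.07) and Idh3b (-0.79). Adjusted over the list alone, 39 and 17 genes were lower and 0 higher. The fatty acid oxidation and peroxisome list was split, with 17 of 35 members lower and 9 higher (20 and 9 adjusted over the list alone), and its set test did not pass (median -0.26, or -0.12 with scaling to library size; camera adjusted p = 0.0859). It did pass without cisplatin replicate 3 (camera adjusted p = 0.0223; 0.0223 to 0.171 over camera's alternatives other than the estimated correlation). Cyp4a14, a fatty acid omega-hydroxylase gene, rose from 139 ± 46 to 928 ± 254 CPM (log2 fold change 2.74).

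Glycolysis genes did not move as a group: 3 of 19 were higher, 5 lower and 11 not called (camera adjusted p = 0.562). Their median was -0.13 and their mean 0.14, and the median was 0.01 with scaling to library size. Hk2 rose from 0.59 ± 0.19 to 4.58 ± 2.69 CPM and Eno2 from 1.66 ± 0.33 to 5.22 ± 0.82 CPM. The lipid synthesis, uptake and storage list had 4 of 26 members higher and 8 lower (median -0.17, or -0.04 with scaling to library size, mean 0.07; camera adjusted p = 0.345, fry 0.0242 for lower). Cidec, a lipid droplet protein gene, rose from 0.80 ± 0.45 to 6.29 ± 1.07 CPM, and Lpl, which encodes lipoprotein lipase, fell from 811 ± 76 to 125 ± 17 CPM. Of the circadian clock genes, 8 of 18 were higher and 7 lower (camera adjusted p = 0.679). Dbp, an output gene of the clock, fell from 209 ± 10 to 55.2 ± 14.1 CPM, and Npas2, a partner of Arntl in the clock's positive arm, rose from 2.03 ± 0.10 to 6.17 ± 1.53 CPM. Adjusted over the list alone, the counts of higher and lower genes were 3 and 5 for glycolysis, 4 and 9 for lipids and 8 and 7 for the clock.

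Of the 30 cell cycle genes, 5 were higher and 25 not called, and none was called when adjusted over the list alone (median 0.41; camera adjusted p = 0.0417, and 0.687 with an estimated correlation). These 5 were a smaller share than the 3326 higher genes among all 14392 tested. Top2a averaged 3.97 ± 1.22 CPM in the controls and 8.74 ± 4.03 CPM in cisplatin, and Prc1 2.62 ± 0.84 and 5.43 ± 1.97 CPM. The Top2a call was lost without control replicate 2, control replicate 3, cisplatin replicate 1 or cisplatin replicate 2 (edgeR adjusted p = 0.121, 0.109, 0.0818 and 0.0781; 0.00389 to 0.121 over all alternatives). The Prc1 call was lost without control replicate 2, control replicate 3 or cisplatin replicate 2 (0.0883, 0.0714 and 0.0663; 0.0106 to 0.0883 over all alternatives). The list's call was lost without control replicate 2 or cisplatin replicate 2 (camera adjusted p = 0.166 and 0.289; 0.00664 to 0.289 over camera's alternatives other than the estimated correlation) and with scaling to library size (0.127), and fry gave 0.253. Extracellular matrix and fibrosis genes were higher in 8 of 23 members and lower in 1 (median 0.49; camera adjusted p = 0.0437, and 0.687 with an estimated correlation). Adjusted over the list alone, 7 were higher and 1 lower. In cisplatin replicate 3 the matrix list lay a median of 0.67, and the cell cycle list 0.57, below the mean of the other 2 cisplatin libraries, and a median of 34.2% of the response was kept over 5 matrix genes changed by at least 2-fold. Timp1 rose from 1.05 ± 0.49 to 16.8 ± 10.3 CPM, and Postn, which encodes the matrix protein periostin, fell by 1.84 on the log2 scale. The matrix list's call was lost without control replicate 1, control replicate 2, cisplatin replicate 1 or cisplatin replicate 2 (camera adjusted p = 0.0747, 0.0973, 0.0605 and 0.184; 0.000318 to 0.184 over camera's alternatives other than the estimated correlation) and without members shared with other lists (0.101), and fry gave 0.253.

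Markers of several tubule segments and of lymphocytes were lower in cisplatin, and podocyte markers were higher. In the thick ascending limb list 5 of 8 markers were lower and none higher (median -1.15; camera adjusted p = 0.000745, and 0.449 with an estimated correlation), with Egf, the epidermal growth factor gene, falling from 1465 ± 183 to 100 ± 31 CPM (log2 fold change -3.87, SE 0.24; edgeR adjusted p = 2.75e-05). In the distal convoluted and connecting tubule list 7 of 9 were lower (median -0.96; adjusted p = 0.00287, and 0.449 with an estimated correlation). On the authors' FPKM plus 1 that median was -0.61, over the members that passed that filter. Pvalb, a calcium-binding protein gene, fell from 33.3 ± 4.8 to 0.91 ± 0.45 CPM, and Trpv5, a calcium channel gene, was the 1 that rose (1.26). Principal cell markers of the collecting duct were lower in 5 of 8 and higher in 1 (median -0.49; adjusted p = 0.0403, and 0.449 with an estimated correlation), with Aqp4 falling by 1.11 and Scnn1b higher by 0.32 on the log2 scale. That list's call was lost without cisplatin replicate 1 (camera adjusted p = 0.106; 0.0209 to 0.106 over camera's alternatives other than the estimated correlation). The Scnn1b call was lost without control replicate 1, 2 or 3 or cisplatin replicate 2 or 3 (edgeR adjusted p = 0.108, 0.0711, 0.0738, 0.0722 and 0.0618; 0.00488 to 0.108 over all alternatives). Intercalated cell markers had 2 of 9 higher and 2 lower (camera adjusted p = 0.808), with Slc4a1, the anion exchanger that red blood cells also carry, falling from 61.8 ± 5.8 to 26.7 ± 2.8 CPM. Podocyte markers were higher in 6 of 9 and lower in none (median 0.66; adjusted p = 0.00296, and 0.449 with an estimated correlation), led by Ptpro (0.89). Adjusted over the list alone, the counts for these 5 cell types were the same.

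Of the T and NK lymphocyte markers, 7 of 8 were lower (median -1.92; camera adjusted p = 0.00306, and 0.468 with an estimated correlation) and 8 adjusted over the list alone. The median was -1.79 with scaling to library size. On the authors' FPKM plus 1 it was -1.14, over the members that passed that filter, which is a different measure. Cd3g, of the T cell receptor complex, fell from 1.95 ± 0.54 to 0.28 ± 0.05 CPM. Red blood cell markers were lower in 6 of 7 (median -8.92, or -7.97 with members at 0 counts in a group at their bound; adjusted p = 0.0366, and 0.468 with an estimated correlation). That call was lost without control replicate 2 or cisplatin replicate 1, 2 or 3 (camera adjusted p = 0.0520, 0.0699, 0.0703 and 0.109; 6.78e-05 to 0.112 over camera's alternatives other than the estimated correlation) and without the member shared with another list (0.112). Epb42 was the member that was higher (0.94), a call lost without control replicate 1 or 3 or cisplatin replicate 2 or 3 (edgeR adjusted p = 0.151, 0.110, 0.114 and 0.104; 0.0263 to 0.151 over all alternatives). In the dendritic cell list 5 of 11 markers were lower, led by the MHC class II gene H2-Aa (158 ± 38 to 57.8 ± 9.2 CPM), and the set test did not pass (camera adjusted p = 0.0512). It passed in 7 alternatives, among them those without control replicate 1, control replicate 2 or cisplatin replicate 2 (camera adjusted p = 0.0399, 0.0220 and 0.0482; 0.0187 to 0.107 over camera's alternatives other than the estimated correlation). B and plasma cell markers had 2 of 5 lower, led by Jchain (-1.49), and Mzb1 higher (0.87), with a camera adjusted p of 0.265. That list passed without the filter on low counts (camera adjusted p = 0.0327) and with fry (0.0382, lower). The Mzb1 call was lost without control replicate 1, 2 or 3 or cisplatin replicate 1 or 2 (edgeR adjusted p = 0.122, 0.104, 0.0723, 0.157 and 0.0527; 0.00574 to 0.157 over all alternatives).

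Macrophage and monocyte markers went both ways, with 4 of 17 higher and 3 lower (camera adjusted p = 0.679). The lysosomal protein gene Cd68 rose from 9.47 ± 1.39 to 78.0 ± 13.9 CPM. Neutrophil markers were higher in 3 of 7 and lower in none (camera adjusted p = 0.212, fry 0.0160 for higher), and S100a9 went from 0.33 ± 0.25 to 1.41 ± 0.40 CPM (log2 fold change 2.08, and 2.88 without control replicate 2). Endothelial markers were lower in 9 of 12 and higher in 1 (median -0.29, or -0.16 with scaling to library size or on the authors' FPKM; camera adjusted p = 0.00720, and 0.449 with an estimated correlation), with the VEGF receptor gene Kdr falling by 1.05 and its relative Flt1 rising by 0.50 on the log2 scale; 10 were lower and 1 higher when adjusted over the list alone. The fibroblast, pericyte and mesangial cell list had 3 of 12 higher and 2 lower (camera adjusted p = 0.629), led by Itga8 (-1.42). Myh11 was also lower (-0.39), a call lost without control replicate 1, 2 or 3 or cisplatin replicate 1 (edgeR adjusted p = 0.0635, 0.156, 0.0658 and 0.145; 0.0224 to 0.220 over all alternatives). Urothelial markers had 1 of 6 lower, Upk2 (1.36 ± 0.55 to 0.30 ± 0.13 CPM), with a camera adjusted p of 0.216. Of the remaining lists, which were too short for a set test, the adipocyte markers had Cidec higher and Fabp4 lower among 3 tested, the adrenal cortex markers Fdx1 lower (-0.73) among 2, and skeletal muscle only Actn3 tested, at 0.96 ± 0.21 and 0.73 ± 0.20 CPM (edgeR adjusted p = 0.366). Ribosomal protein genes had 10 of 30 higher and 1 lower (8 and 0 adjusted over the list alone), and 4 Y-linked genes had none called (median log2 fold change 0.11).

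**Figure D2:**
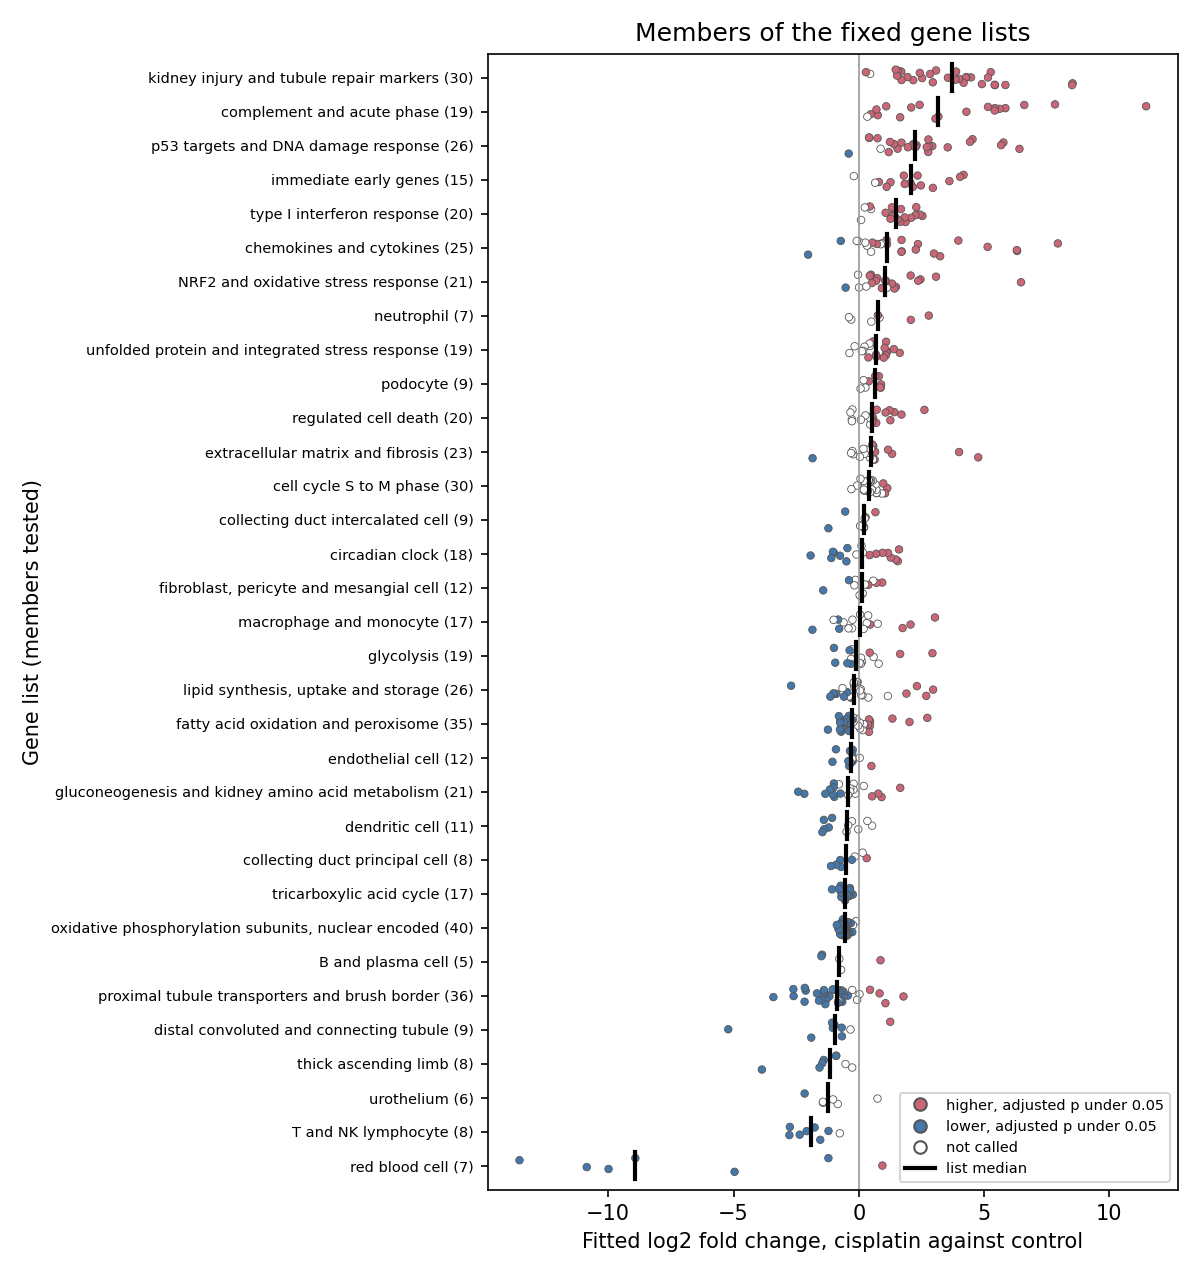
Fitted log2 fold change (cisplatin against control) of each tested member of the gene lists with at least 5 tested members; a point is a gene, filled where its adjusted p was under 0.05, and the black bar is the list median. Medians run from -8.92 for red blood cell markers to 3.71 for kidney injury markers, and values of genes with no count in a group, such as Saa1 and Hba-a2, depend on the fit's prior count.

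Of the 33 lists long enough for the set test, camera with the preset correlation called 12 higher and 10 lower in cisplatin, and with an estimated correlation it called 0 and 0. The directional test fry, which asks whether a list's own genes move one way, called 11 higher and 11 lower.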

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

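The 4 counts of called genes stayed within 1.5 times their values under every alternative except limma on the authors' FPKM, where 2080 genes were lower (3201 with edgeR on the counts) and 329 lower by at least 2-fold (772). That setting applies no composition factors, and adding 1 before the log2 shrinks changes at low values. How much each contributes was not tested. Fewer genes (12385) passed that filter, yet 4170 were called higher (3326 with edgeR on the counts). Scaling to library size only gave a similar balance, with 2281 lower and 67.0% of the called genes higher, against 66.7% on FPKM. Leaving out 1 library gave 2486 to 3614 higher and 2281 to 3591 lower genes, and 964 to 1217 and 704 to 948 by at least 2-fold. Rarres2 kept its direction and its call under all alternatives, with log2 fold changes of 0.89 to 1.25 and adjusted p from 2.18e-06 to 0.0286. Camera with an estimated correlation called 0 lists higher and 0 lower (12 and 10 with the preset correlation). The size of the correlation is not the whole cause. For the unfolded protein and integrated stress response list it was estimated at 0.0092, under the preset 0.01. That list's camera adjusted p still went from 8.56e-05 to 0.149. What else differs between these settings was not tested. Other alternatives, fry included, called 10 to 12 lists higher and 8 to 12 lower. Apart from the estimated correlation, 10 of 33 lists crossed the threshold in some setting, and none called in any setting turned its direction. Of the 74 other named genes tested, 16 lost their call in some setting and none that was called turned its direction. Camera already runs on voom values and was not run with DESeq2.

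Samples of the same replicate number did not deviate together across genes (correlations of 0.04, -0.14 and -0.16), so the numbers were not taken as pairs. With the replicate number as a block, 2822 genes were higher and 2739 lower, 1029 and 769 by at least 2-fold, and Rarres2 had a log2 fold change of 1.15. No control correlated best with the cisplatin library of its own number except control replicate 1. At this depth genes with a few counts per library were limited, as the wide interval for Gpr1 shows.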

Other observations

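Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes as the real split. That was the real split itself, with 6527 genes against at most 0 in the others. Every other split mixed control and cisplatin libraries in both groups, which puts the treatment difference into the spread within groups. Low counts there were thus built in, and 10 splits are too few for a share under 0.05. No conclusion on chance is drawn from the splits. The gene families described here, and the tests of lymphocyte markers, of globins and platelet genes, of mixed RNA and of the length trend over classes, were chosen only after the data were seen. The tests of the splits, transcript length, GC content, cell type loss and cortex were written before their own values were seen. The fall of long genes and the place of cisplatin replicate 3, which all of these but the splits address, were themselves patterns found in the data. Among SLC22 genes, which encode transporters of organic anions and cations, 17 of 22 tested were lower in cisplatin, 1 was higher and 4 were not called (median log2 fold change -1.03). The falls included Slc22a28 (-3.63), Slc22a22 (-2.79) and Slc22a26 (-2.58), and the member that rose was Slc22a15 (1.02). Of 78 genes for mitochondrial ribosomal proteins, 44 were lower and 2 higher (median -0.28), the latter being Mrpl33 (0.87) and Mrps18b (0.52). Glutathione S-transferase genes went both ways, with 10 of 20 higher, among them Gstp3 (3.36) and Gstm6 (2.56), and 3 lower. Claudins, which form tight junctions, had 7 of 16 higher, including Cldn4 (2.88) and Cldn1 (2.46), and 3 lower, including Cldn18 (-2.36). Each of these medians kept its sign under the other scalings tried, which moved the median of all genes by up to 0.14, though that of the mitochondrial ribosomal genes was -0.14 with scaling to library size.

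Of 9 MHC class II genes and their invariant chain, 6 were lower and none higher (median -1.20), while of 14 MHC class I heavy chain genes 6 were higher and none lower (median 0.28). H2-D1 and H2-K1 rose by 0.77 and 0.69 on the log2 scale, and H2-Ob fell by 1.56. Class I genes are near-identical and can share reads. Of the 38 proteasome subunits, 7 were higher, among them the 3 immunoproteasome subunits Psmb8 (0.78), Psmb9 (0.68) and Psmb10 (1.14), and 1 was lower. Over all 14392 genes tested 3326 were higher and 3201 lower, larger shares than among these subunits. Of 8 aquaporins, 3 were higher (Aqp8 by 3.34, Aqp6 by 0.66 and Aqp7 by 0.40 on the log2 scale) and 4 lower (Aqp1, Aqp3, Aqp4 and Aqp11). Loci with predicted gene symbols (Gm followed by a number, 307 tested) took 0.82% ± 0.05 of normalized counts in the controls and 2.20% ± 0.07 in cisplatin (SD, n = 3 per group). Only 61 of them were higher and 40 lower, both under the shares over all genes.

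Very long genes were lower in cisplatin: of 348 tested genes over 320 kb, 178 were lower and 28 higher, and the median log2 fold change fell from -0.03 at 80 to 160 kb to -0.13, -0.45 and -0.63 in the next 3 classes, the last being 79 genes such as Fhit, Immp2l (-5.55) and Wwox (-3.39). Matching to genes under 80 kb argued against transcript length and GC content as the whole cause, since the difference of -0.50 became -0.58 (95% interval over draws -0.63 to -0.54) after matching on the first and -0.52 (-0.56 to -0.47) on the second. Fewer completed transcripts of long genes, as DNA adducts that block RNA polymerase could give, and loss of the cell types that use long genes cannot be told apart here. A least-squares model with transcript length, GC content and expression gave mean differences from genes under 20 kb. Its coefficient fell to -1.24 (SE 0.17, bootstrap over genes) in the longest class. That coefficient is a mean with another reference, so its size cannot be set against the medians above. It restates the fall with length and is not specific to either explanation. Within cell type lists, length did not go with the deviation from the list's median (Spearman's rho -0.0091, permutation p = 0.907, 121 genes), which is what a loss of cells predicts, but only 6 of these markers exceeded 160 kb, a reading settled after the value was seen. Neither unspliced reads nor the time since injection could be examined here.

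Globin transcripts summed to 710, 285 and 55.5 CPM in the control libraries and to 0.30, 0.30 and 0.51 CPM in the cisplatin libraries, so the lowest control lay 109 times above the highest cisplatin library. Less blood left in the kidneys would lower transcripts of other blood cells alike. Platelet genes argued against it as the whole cause: the 11 of them summed to 12.2 ± 0.8 CPM in the controls and 10.8 ± 0.6 CPM in cisplatin (SD, n = 3 per group), a ratio of 1.13 where the globins need at least 109. Without the 2 most abundant genes the sums were 1.95 ± 0.36 and 1.51 ± 0.35 CPM, on 95 and 87 counts. The highest control then lay 2.06 times above the lowest cisplatin library. The lymphocyte markers had a 3.78-fold median fall. Their median log2 fold change of -1.14 on the authors' FPKM plus 1 was over members passing that filter, a different measure. These sums rest on few counts and did not follow globin among the controls either (2.32, 1.59 and 1.93 CPM). No conclusion on the fall of the lymphocyte markers is drawn from them. Both comparisons also assume that platelet genes have no source in kidney tissue. Within the controls the called lymphocyte markers summed to 18.9, 9.92 and 26.1 CPM in replicates 1 to 3, so they ran against globin in 2 of 3 pairs. Replicate 1 had 12.8 times the globin of replicate 3 with a median log2 ratio of these markers of -0.36 (0 of 7 higher), and 2.49 times that of replicate 2 with a ratio of 0.78. Less blood left in the kidneys and fewer young red blood cells in the circulation both stay open, and the latter was not tested.

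Cisplatin replicate 3 lay nearer to the controls than the other 2 cisplatin libraries. RNA of a control kidney mixed into it would lower every response by 1 common share, but it kept a median of 86.3% of the response for 21 p53 targets and 51.3% for 28 injury markers, a difference of 35.0 percentage points (permutation p = 9e-05 over genes, which are not independent replicates), which argues against mixing as the whole cause. More cortex in the sampled piece cannot be told apart from a milder injury: podocyte markers lay 0.06 above the mean of the other 2 libraries and principal cell markers 0.13 above it, with a lower quartile at about 0 and an upper quartile of 0.25, while thick ascending limb markers lay 0.57 below. The rule written before this value was seen counted any principal cell median at or above 0 against more cortex. The spread over members, which reaches 0, was brought in only after the value was seen. A weaker or later response in that sample is a biological explanation that was not tested.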
